A study of Arabidopsis thaliana with 15 samples.

How the data were processed

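Transcript abundance was measured by RNA sequencing in 10-day-old Arabidopsis thaliana seedlings. The labels describe 15 samples in 5 groups, and files of 13 of them were used. The groups were wild type (WT, accession Col-0) at room temperature (1 library), after heat (3 libraries) and after recovery (3 libraries), and the siz1-2 mutant at room temperature (3 libraries) and after heat (3 libraries). WT room-temperature replicates 1 and 3 were not analysed here. Total RNA was extracted with TRIzol and made into libraries with a TruSeq RNA kit, per the labels' protocols.

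The deposited values were FPKM (fragments per kilobase of transcript, scaled to library size) of each transcript, written by Cufflinks per the file contents, with confidence limits and a coverage value. Reads were aligned with HISAT2 2.1.0 to the TAIR10 genome, and Cuffdiff 2.1.1 was also named, per the submitters' processing notes; the Cufflinks version is not given in the sources used here. The file contents showed that the WT and siz1-2 files had been made in different ways. WT files held transcripts assembled on chromosomes, 25535 to 26497 per library. Of these, 1690 to 2350 per library covered at least 50% of the exons of more than 1 annotated gene. The siz1-2 files held only transcripts on annotated cDNA sequences, each named by its gene, 17447 to 17972 per library. On such sequences no transcript can lie across more than 1 gene. In 3 siz1-2 libraries the deposited confidence limits left out the FPKM value itself for 28.5 to 33.2% of transcripts. WT recovery replicate 1 held 4 transcripts with extreme FPKM, which made up 97.2% of its FPKM sum.

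Because WT transcripts carried no gene identifiers that could be used across libraries, each transcript was placed on the TAIR10.1 annotation by its exons. Chromosome ends fitted the TAIR10.1 lengths, and 115445 of 125029 introns (92.3%) of assembled transcripts had GT-AG ends on that sequence. The value of a gene was the sum of the FPKM of its transcripts, weighted by length. In WT each FPKM was multiplied by the transcript's exon length on the gene. The sum was divided by the length covered by all exons of the gene. In the mutant each FPKM was multiplied by the transcript's length, and the sum was divided by the length of the gene's longest annotated transcript. For genes with several isoforms this weighting can thus differ between genotypes in its divisor. This weighting was chosen after the files were seen, on the agreement of replicates and the number of genes listed and before any test; the design had stated only that isoforms would be summed. A gene is called joined below where an assembled WT transcript covered at least 50% of its exons and of a neighbour's. It is also called joined where at least 50% of its value in a WT library came from transcripts lying mostly on another gene. In all, 5635 genes were joined, and a joined gene's WT value can hold its neighbour's reads. Smaller sharing was not flagged, so a gene not called joined can hold such reads too. The labels do not say that reads kept their strand, so values of antisense partners and of near-identical family members are uncertain too.

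The files held no read counts. The ratio of coverage to FPKM within each file implied 6.62 to 11.4 Gb of aligned sequence per library, and the median half-width of the deposited confidence interval was 9.30 to 15.7% of FPKM. Values were scaled across libraries by median-ratio factors of 0.56 to 1.40 and transformed as log2(scaled FPKM + 1). The lowest factor, 0.56, was that of the single WT room-temperature library, and the other WT libraries had 0.729 to 1.147. In siz1-2 the factors were 1.397 to 1.403 at room temperature and 0.987 to 1.044 after heat. A fold change on this scale understates the change of a gene with a low value. A gene was tested if it was listed in every file and its mean scaled FPKM was at least 1, which left 11603 genes. A gene absent from a file was treated as not listed, not as 0.

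Groups were compared in 1 limma 3.58.1 fit of all 13 libraries (R 4.3.3; a mean per group, eBayes with a trend, 8 residual degrees of freedom), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05, two-sided. The 7 comparisons were heat in WT, heat in siz1-2, recovery against heat in WT, recovery against room temperature in WT, siz1-2 against WT at room temperature, siz1-2 against WT after heat, and the difference between genotypes in the response to heat (the interaction). The WT room-temperature group held 1 library, which is assumed to vary like the other groups. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Errors are SD of scaled FPKM or SE of log2 changes.

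The groups, the comparisons, the filter, the threshold, the gene lists and the rule for naming genes were fixed before the data were examined. The 18 lists covered heat stress factors, small heat shock proteins, larger chaperones (HSP100, HSP90, HSP70, HSP60 and co-chaperones), the unfolded protein response, the SUMO pathway, salicylic acid and immunity, phosphate starvation, photosynthesis, growth by auxin and brassinosteroid, the circadian clock, flowering time, reactive oxygen, abscisic acid with cold and drought, jasmonate and wounding, ribosomal and nucleolar proteins, the cell cycle, root markers and seed maturation markers. Each list was counted over all genes tested and with adjustment over the list alone, and tested against other genes with limma's camera at its preset correlation and again with an estimated one. The naming rule took up to 6 genes per direction and comparison with the largest called change, a mean of at least 5 in the higher group and no overlap of libraries, then up to 3 called members per list, at most 25 genes in all; SIZ1, HSFA2, HSP101, HSP70-4, BIP3, PR1 and FLC were always looked up, and some names are left out below for length.

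The fit was tested on simulated data with 50 genes changed at each size among 11603, drawn with the same normal spread per gene in every group. In the data the spread differed between groups (median SD of log2 values 0.272 in heated WT and 0.095 in siz1-2 at room temperature). The shares below therefore hold only for equal spread. For heat in siz1-2, 82% of genes changed by 1 on the log2 scale and 96% of those changed by 2 were recovered, with 7 false calls; the shares were 38% and 96% for heat in WT (13 false calls), 72% and 98% for recovery against heat (11), and 16% and 90% for the interaction (7). Other settings fixed beforehand were FPKM as deposited, TPM, quantile normalization, other pseudocounts and filters, unlisted genes kept as 0, a replicate block, fits of only the groups compared, a fold threshold, and leaving out each replicate. Settings added after seeing the data were a single gene per transcript, leaving out joined genes, genes with 1 isoform only, and leaving out WT heat replicate 3 and WT recovery replicate 1 together. Chance overlap of comparisons that share a control, and the share of a heat change that noise alone would keep, were simulated 50 times each; the latter was added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.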

Results

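The series asked how SUMO, a small protein attached to other proteins, bears on the switch of plant transcription between development and the response to heat. Seedlings grew for 10 days at 23 °C under 16 h of light and 8 h of dark. They were kept at room temperature, placed for 30 min in a water bath at 37 °C, or returned to 23 °C for 90 min after that heat. The mutant siz1-2 carries a T-DNA insertion in SIZ1, which encodes a SUMO E3 ligase. Of 15 samples described, 13 were used here: 1 WT library at room temperature, 3 each of heated and recovering WT, and 3 each of siz1-2 at room temperature and after heat. Depth ranged from 6.62 Gb implied for WT heat replicate 3 to 11.4 Gb for WT recovery replicate 3, and 22121 genes had a value in at least 1 library.

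SIZ1 itself (AT5G60410, chromosome 5, 24294704 to 24301157 in the TAIR10.1 annotation) had 22.46 scaled FPKM in the WT library at room temperature. It had 26.27, 22.14 and 21.28 in heated WT and 19.76, 18.53 and 20.98 in recovering WT. SIZ1 was not listed in any of the 6 siz1-2 libraries. This is a weak check of the labels, because SIZ1 has 6 annotated isoforms and siz1-2 files often lacked such genes. Among genes with a median WT FPKM of at least 10, here with each transcript placed whole on a single gene, all 6 siz1-2 files listed 3526 of 3563 with 1 isoform and 1045 of 1907 with 2. They listed 300 of 823 with 3 isoforms and 161 of 736 with 4 or more. HSFA2 (AT2G26150, chromosome 2, 11135624 to 11137792, 4 isoforms), a heat stress factor that prolongs the heat response, and BIP3 (2 isoforms), a chaperone of the endoplasmic reticulum, were not listed in siz1-2 either and not tested. BIP3 had 1.29 scaled FPKM in WT at room temperature and 3.78, 1.71 and 1.69 after heat, so low expression is not separated from the number of isoforms as the reason. FLC (AT5G10140, chromosome 5, 3173382 to 3179448), a repressor of flowering, had 1.56 to 3.44 in WT and was listed in siz1-2 only at 0.50 and 0.65 in room-temperature replicates 2 and 3.

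Heat genes separated the library labelled WT heat replicate 3 from the other WT heat libraries. HSP101 (AT1G74310, chromosome 1, 27936508 to 27940369, joined), the disaggregase needed for thermotolerance, had 2.83 scaled FPKM in WT at room temperature and 1239 and 3229 in heat replicates 1 and 2, but 2.59 in the library labelled WT heat replicate 3. HSFA2 had 415 and 2668 in the first pair and 0.49 in that library, and HSP70-4, a cytosolic HSP70, had 2304 and 5013 against 7.55. Across 194 genes that rose at least 4-fold in heated siz1-2, the median log2 difference from the WT room-temperature library was 2.14 and 3.41 in heat replicates 1 and 2 and -0.04 in the library labelled WT heat replicate 3. Correlations across genes, which are not independent replicates, were 0.869 to 0.954 within heated WT, 0.945 to 0.952 within recovering WT and 0.991 to 0.996 within heated siz1-2. The comparisons below keep all 13 libraries, as fixed beforehand, and also give values without that library. Leaving out each replicate in turn was planned. Giving this fit beside the main one, with its list tests, was chosen after the heat genes of that library were seen. The choice favours calls of heat genes in WT, so these calls are not an independent test of the heat response.

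**Figure D1:**
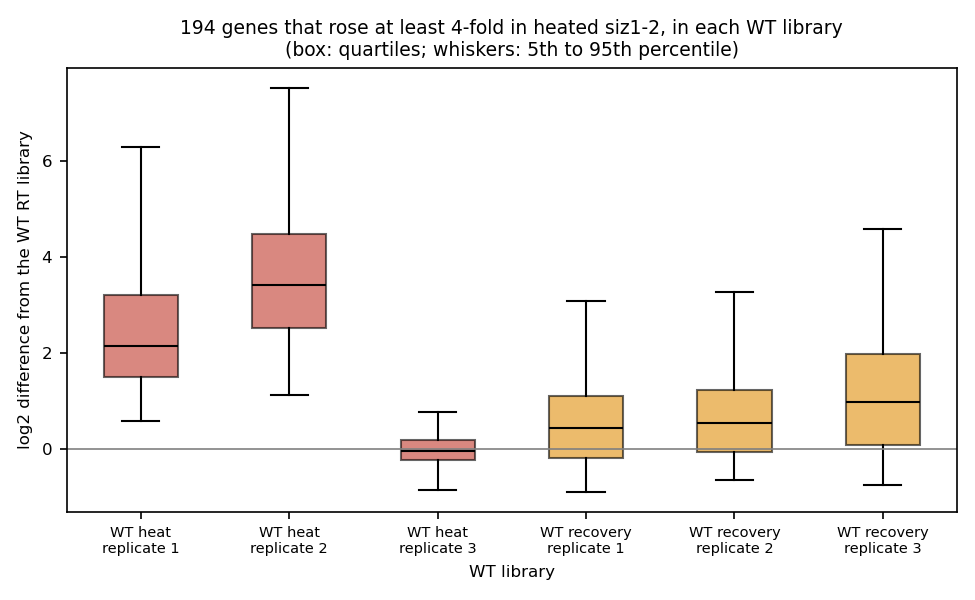
Log2 difference from the WT room-temperature library of 194 genes that rose at least 4-fold in heated siz1-2, for each WT heat and recovery library; boxes are quartiles, black lines medians and whiskers the 5th to 95th percentile. The medians were 2.14, 3.41 and -0.04 in the libraries labelled WT heat replicates 1, 2 and 3, and 0.45, 0.55 and 0.98 in WT recovery replicates 1, 2 and 3.

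**Figure D2:**
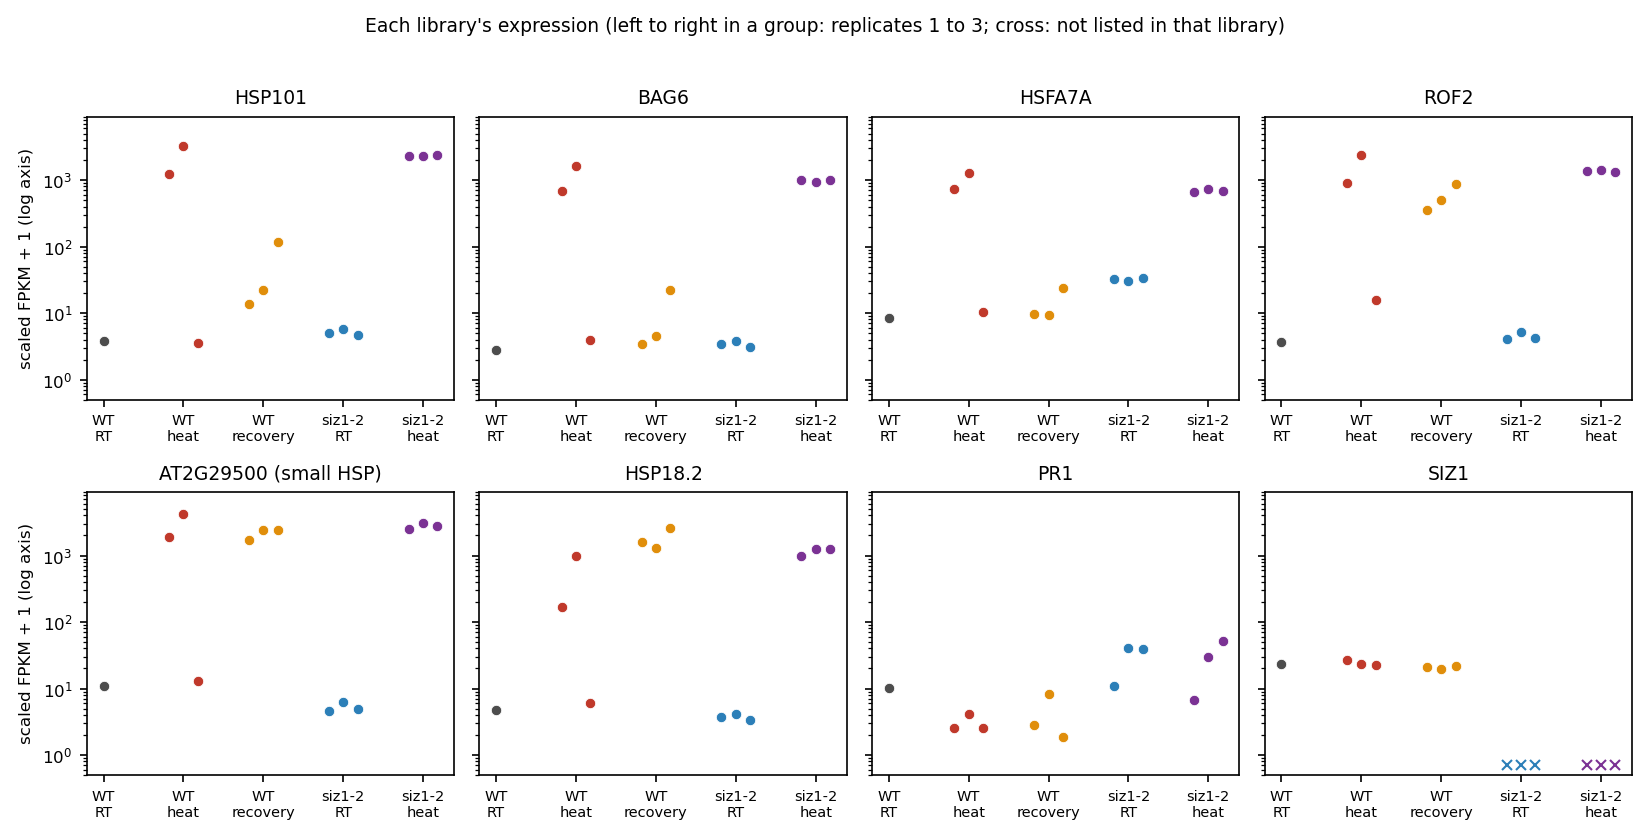
Scaled FPKM plus 1, on a log axis, of 8 genes in each library; each point is a library, placed left to right by replicate number, and a cross marks a library in which the gene was not listed. HSP101 reached 1239 and 3229 in WT heat replicates 1 and 2 and 2.59 in the library labelled WT heat replicate 3, and SIZ1 was not listed in siz1-2.

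Heat in siz1-2 raised chaperone mRNAs steeply within 30 min. AT1G53540, a cytosolic small heat shock protein, rose from 1.3 ± 0.535 to 2975 ± 289 scaled FPKM (SD, n = 3 each; log2 change 10.36, SE 1.94, adjusted p = 0.011). AT2G29500 (chromosome 2, 12633065 to 12634120), another of this family, rose from 4.27 ± 0.877 to 2802 ± 278 (log2 change 9.06, SE 1.59, adjusted p = 0.00976). HSP101 rose from 4.13 ± 0.573 to 2341 ± 56.6 (log2 change 8.84, SE 1.94, adjusted p = 0.0168). ROF2, a peptidyl-prolyl isomerase that acts with heat shock proteins, rose from 3.52 ± 0.625 to 1390 ± 48.4, and BAG6, a co-chaperone of HSP70, from 2.45 ± 0.335 to 974 ± 30.6 (log2 changes 8.27 and 8.15). Among regulators, HSFA7A rose from 31.4 ± 1.79 to 693 ± 36.7 and HSFB2A from 4.04 ± 0.278 to 145 ± 6.98. In all, 2232 genes passed, 1055 higher and 1177 lower after heat, and 735 of these changed at least 2-fold, 438 upwards and 297 downwards. Calls here depended on which library was left out: without any 1 of the 6 siz1-2 libraries limma no longer called HSP101, BAG6, HSFB2A or HSFA7A (adjusted p up to 0.0638, 0.0595, 0.0654 and 0.121), and 245 to 569 genes passed. HSFA7A was also lost without any 1 of the 3 WT recovery libraries, and AT1G53540 without siz1-2 room-temperature replicate 3 (adjusted p = 0.0513), while AT2G29500 and ROF2 passed in each fit without 1 library. The SE in these fits also holds the spread of heated WT, where the library labelled replicate 3 had HSP101 near its room-temperature level. In a limma fit of the siz1-2 libraries alone HSP101 had a log2 change of 8.89 (SE 0.09, adjusted p = 6.03e-11).

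By list, 14 of 17 larger chaperones rose in siz1-2 and 0 fell (16 adjusted over the list alone; camera adjusted p = 2.91e-09, and adjusted p = 0.557 with an estimated correlation). Of 9 small heat shock proteins 6 rose and 1 fell, AT4G21870 (54.1 ± 0.33 to 39.3 ± 6.16), with the same counts adjusted over the list alone (camera adjusted p = 0.00811, and adjusted p = 0.67 with an estimated correlation). Of 11 heat stress factors 5 rose (8 adjusted over the list alone), and of 10 genes of the unfolded protein response 3 rose (5 adjusted over the list alone), among them BIP1, the HSP70 of the endoplasmic reticulum (88.4 ± 6.09 to 333 ± 16.8). Of 7 genes of the reactive oxygen list 5 rose and 1 fell, both over all genes and adjusted over the list alone; the zinc finger factors ZAT12 and ZAT10 had log2 changes of 4.54 (SE 1.22) and 2.93 (SE 0.49). PRR7, a repressor in the circadian clock, rose from 0.919 ± 0.394 to 39.8 ± 5.71, and 2 of 7 clock genes rose and 1 fell (4 and 1 adjusted over the list alone). TCH4, a cell wall enzyme induced by touch, rose from 20.4 ± 1.73 to 383 ± 129 and was the 1 of 6 genes of the jasmonate and wounding list to rise (2 adjusted over the list alone). GOLS2, which makes the osmoprotectant galactinol, had a log2 change of 3.92 (SE 0.76), and the dehydrin COR47 was 1 of 2 that rose among 9 genes of abscisic acid, cold and drought (5 adjusted over the list alone). Without any 1 of the 6 siz1-2 libraries 3 to 8 larger chaperones, 4 to 6 small heat shock proteins, 1 to 4 reactive oxygen genes and 1 clock gene rose. Limma then called 0 heat stress factors (6 to 8 higher at an unadjusted p under 0.05) and 0 genes of the unfolded protein response (3 to 5), of jasmonate (1 to 3) and of abscisic acid (2 to 5). The calls of BIP1, ZAT12, TCH4 and COR47 were lost in each of those 6 fits (adjusted p up to 0.104, 0.092, 0.0808 and 0.0748). BIP1 was also lost without WT heat replicate 1, and GOLS2 without siz1-2 room-temperature replicates 2 and 3 (up to 0.055). AT4G21870 was lost without siz1-2 room-temperature replicates 1, 2 and 3 and siz1-2 heat replicates 1 and 3 (adjusted p up to 0.11). Heat stress factors that rose numbered 5, 8 and 8 without WT heat replicates 1, 2 and 3 in turn, with 1 lower in the first. They numbered 3, 3 and 4 without WT recovery replicates 1, 2 and 3. Genes of the unfolded protein response that rose numbered 1, 5, 5, 3, 2 and 2 in these 6 fits.

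The largest falls in siz1-2 were smaller than the rises. ZFP6, a zinc finger protein, fell from 18.8 ± 2.78 to 2.45 ± 0.432 scaled FPKM (log2 change -2.52, SE 0.46, adjusted p = 0.0101). The abscisic acid receptor PYL6 fell from 16.8 ± 1.38 to 2.61 ± 0.55, and IAA29, a repressor of auxin signalling, from 9.04 ± 4.27 to 1.94 ± 0.224. Of 20 growth genes 1 rose and 2 fell (3 and 2 adjusted over the list alone), although with FPKM as deposited 0 rose and 4 fell. Of 18 genes of salicylic acid and immunity 0 rose and 3 fell (1 adjusted over the list alone), with 0 and 9 for FPKM as deposited. Of 8 cell cycle genes 1 fell, and of 9 root markers 2 fell, with 0 higher and the same counts adjusted over the list alone. Of 17 phosphate genes 2 rose (1 adjusted over the list alone), while their median moved from 0.13 to -0.30 with FPKM as deposited and to -0.33 with TPM. Photosynthesis depended on the scaling: 11 of 18 genes rose and 0 fell in the main scaling (14 adjusted over the list alone), but 3 rose and 1 fell with FPKM as deposited, 1 rose with TPM and 3 rose and 2 fell with quantile normalization. Of the other lists, limma called 0 of 12 SUMO pathway genes (4 at an unadjusted p under 0.05), 0 of 3 flowering genes (0 at that p) and 0 of 9 ribosomal genes (1 at that p). SUMO pathway genes that rose numbered 2 without WT heat replicate 2 and 3 without the library labelled WT heat replicate 3. Without WT recovery replicate 1 or siz1-2 heat replicate 3, 1 of them fell. No seed maturation marker could be tested (0 of 10). PR1 had a log2 change of -0.26 (SE 0.77, adjusted p = 0.833). ZFP6 and IAA29 passed without any 1 library, and PYL6 was lost without siz1-2 room-temperature replicates 2 and 3 and each siz1-2 heat replicate (adjusted p up to 0.0622). Without any 1 siz1-2 library 2 to 4 photosynthesis genes rose, and 2 growth genes and 1 or 2 immunity genes fell. Limma then called 0 phosphate genes higher (2 or 3 at an unadjusted p under 0.05), and 0 cell cycle genes (1) and 0 root markers (2 to 5) lower. Without WT heat replicate 2, 4 growth genes rose and 4 fell, and 4 root markers fell. Without the library labelled WT heat replicate 3, 4 growth genes rose and 3 fell.

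Heat in siz1-2 was called in more genes when the spread was taken from siz1-2 alone, at 7978 of 14282 genes. In that fit HSP70-4 had a log2 change of 8.26 (SE 0.10), HSP90.1, a cytosolic HSP90, 8.90 (SE 0.09) and MBF1C, a heat-induced coactivator, 8.27 (SE 0.15). The SUMO pathway then had 5 of 13 genes higher and 2 lower, among them ESD4, a SUMO protease, at 0.68 (SE 0.08), and SUMO3 at -0.57 (SE 0.19). With FPKM as deposited 4288 genes were called and 11.4% rose, and with TPM 3336 and 12.3%, against 47.3% here, as the median of all genes moved by -0.39 and -0.43. The count was 3761 without the library labelled WT heat replicate 3 and 3626 without WT heat replicate 2. It was 569, 282 and 245 without siz1-2 room-temperature replicates 1, 2 and 3, and 435, 380 and 479 without siz1-2 heat replicates 1, 2 and 3.

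Heat in WT was assessed against the single room-temperature library. The genes called across all 3 heat libraries were largely not chaperones. LHCB3 (chromosome 5, 22038165 to 22039568), a light-harvesting protein of photosystem II, fell from 848 to 388 ± 26.1 scaled FPKM (n = 1 and 3; log2 change -1.13, SE 0.19, adjusted p = 0.0226). LSU1, induced under sulfur shortage, rose from 5.97 to 33.0 ± 14.5 (log2 change 2.2, SE 0.38, adjusted p = 0.0252), and SERAT3;2, a serine acetyltransferase of cysteine synthesis whose gene was joined, from 0.712 to 28.4 ± 7.34. AT5G60650 (chromosome 5, 24374179 to 24374798, joined) rose from 2.16 to 58.2 ± 1.46, and AT5G02950 (chromosome 5, 690685 to 693099) fell from 15.3 to 0.579 ± 0.363. HSP101 had 1490 ± 1628 after heat, a log2 change of 5.99 that did not pass (SE 2.75, adjusted p = 0.292), and PR1 had -1.76 (SE 1.09, adjusted p = 0.413). In all 100 genes passed, 74 higher and 26 lower, and 36 of them were joined. The library labelled WT heat replicate 3, whose heat genes were at room-temperature levels, had at least 50% of the log2 change of the other heat libraries in all 100 of these genes, and the recovery mean had it as well in 78. These genes were called with that library in the heat group, which favours genes where it agrees, so its share was largely set by the call. As the library labelled WT heat replicate 3 lacked the heat response, none of these 100 changes need be a response to heat. For the 78 shared by recovery, the single room-temperature library may also stand apart. In the rest the recovery mean had under 50% of the change, as for AT5G60650 and AT5G02950, at 0.18 and 0.02 (log2) from room temperature. In a limma fit of the WT room-temperature and heat libraries alone 0 of 16902 genes passed (689 at an unadjusted p under 0.05). LSU1 lost its call without siz1-2 room-temperature replicate 3 and siz1-2 heat replicates 1 and 3 (adjusted p up to 0.0561), and LHCB3 without siz1-2 room-temperature replicates 2 and 3 and siz1-2 heat replicate 1 (up to 0.0558).

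With all libraries limma called 0 of 17 larger chaperones in WT (8 at an unadjusted p under 0.05), 0 of 9 small heat shock proteins (3 at that p) and 0 of 11 heat stress factors (1 at that p). Without the library labelled WT heat replicate 3, 2088 genes passed, 1064 higher and 1024 lower, and 15 of 18 larger chaperones (17 adjusted over the list alone), 7 of 10 small heat shock proteins (7) and 5 of 11 heat stress factors (5) rose with 0 lower. HSP101 then had a log2 change of 9.02 (SE 0.97, adjusted p = 0.00048), AT2G29500 8.03 (SE 0.40) and HSFA7A 6.83 (SE 0.50). PS2, a phosphatase induced by phosphate starvation, had 3.86 (SE 0.61, adjusted p = 0.00334), and 4 of 17 phosphate genes rose (5 adjusted over the list alone). Of 20 growth genes 4 fell without that library (7 adjusted over the list alone), among them IAA29 at -1.54 and YUC8, an enzyme of auxin synthesis, at -0.91. With all libraries limma called 0 of them (10 at an unadjusted p under 0.05), and 2 fell adjusted over the list alone. Of 10 genes of the unfolded protein response 5 rose without it (8 adjusted over the list alone), and of 18 photosynthesis genes 3 fell (4 adjusted over the list alone). Root markers, a list for the share of organs in a sample, changed beside these, with 1 of 9 higher, EXPA7 at 0.90, and 2 lower, SCR at -0.94 and COBL9 at -1.22 (1 and 3 adjusted over the list alone). With FPKM as deposited 4147 genes were called and 99.5% rose, with TPM 22 and 40.9%, and with quantile normalization 159 and 60.4%, against 74% here, as the median of all genes moved by 0.60 and -0.16 in the first pair. The count also fell to 66, 56 and 55 without siz1-2 room-temperature replicates 1, 2 and 3 and to 57 and 61 without siz1-2 heat replicates 1 and 3, and was 166 and 151 without WT recovery replicates 1 and 2.

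Recovery against heat in WT compared 3 libraries with 3 and asked what 90 min at 23 °C undid. Of 20 growth genes 9 rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 0.00014, and adjusted p = 0.504 with an estimated correlation), and 6 to 9 rose with 0 lower in the other scalings. YUC8 rose from 1.90 ± 0.882 to 4.46 ± 0.737 scaled FPKM (SD, n = 3 each; log2 change 0.95, SE 0.19, adjusted p = 0.0114). PIN3, an auxin exporter, rose from 19.9 ± 7.76 to 44.4 ± 12.3, and SAUR20, a small auxin-induced RNA, from 3.99 ± 0.3 to 8.71 ± 1.1. Of 17 phosphate genes 3 fell and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.0546, and adjusted p = 0.757 with an estimated correlation), with PS2 from 66.3 ± 41.1 to 10.8 ± 5.31 and the phosphate sensor SPX1 from 96.7 ± 51.8 to 35.2 ± 17.3. Of 8 cell cycle genes 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0131, and adjusted p = 0.504 with an estimated correlation), a count that was 1 with FPKM as deposited and 0 with TPM. ACS7, an enzyme of ethylene synthesis, fell from 29.8 ± 28.9 to 2.09 ± 0.253, and CT-BMY, a chloroplast beta-amylase, rose from 13.4 ± 11 to 73.3 ± 36.7. Without WT heat replicates 1, 2 and 3 in turn, 6, 5 and 13 growth genes rose, and without WT recovery replicates 1, 2 and 3, 4, 5 and 7. Phosphate genes that fell numbered 0, 1, 6, 0, 1 and 2 in these 6 fits (limma; 6, 6, 6, 5, 5 and 7 at an unadjusted p under 0.05), and cell cycle genes 2, 1, 4, 4, 2 and 2. PIN3, SAUR20 and PS2 lost their calls without WT heat replicates 1 and 2 and WT recovery replicate 1. PIN3 also did so without WT recovery replicate 3, and SAUR20 and PS2 without WT recovery replicate 2 (adjusted p up to 0.0632, 0.0574 and 0.0781). SPX1 was lost without WT heat replicate 1, WT recovery replicates 1 and 3 or any 1 siz1-2 library (up to 0.149), and ACS7 without WT heat replicate 1 (0.0567).

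In all 1718 genes passed, 983 higher and 735 lower in recovery. In a limma fit of these 6 WT libraries alone 15 of 15705 passed (2770 at an unadjusted p under 0.05). The fit of all 13 libraries also draws on the spread of siz1-2 libraries: the median SD of log2 values was 0.272 and 0.202 in heated and recovering WT, and 0.095 and 0.11 in siz1-2 at room temperature and after heat. Of 9 root markers 2 rose and 0 fell (3 adjusted over the list alone; camera adjusted p = 0.228, and adjusted p = 0.882 with an estimated correlation). The count was 4 without the library labelled WT heat replicate 3, 0 without WT recovery replicate 3 (limma; 3 at an unadjusted p under 0.05), 2 without siz1-2 heat replicate 2 and 1 without any 1 of the others. Of 11 heat stress factors 2 fell (3 adjusted over the list alone). Of 18 immunity genes 2 rose and 2 fell, the same adjusted over the list alone, and of 7 reactive oxygen genes 1 rose and 2 fell (1 and 3). In these libraries limma called 0 of 17 larger chaperones (3 at an unadjusted p under 0.05) and 0 of 9 small heat shock proteins (2 at that p), whose median was -0.32 and mean 0.77. HSP101 had a log2 change of -2.87 (SE 1.94, adjusted p = 0.314) and PR1 0.22 (SE 0.77, adjusted p = 0.857). Without the library labelled WT heat replicate 3 the count was 4249. Then 13 of 18 larger chaperones (16 adjusted over the list alone) and 7 of 11 heat stress factors (7) fell with 0 higher, and of 10 small heat shock proteins 1 rose and 3 fell (1 and 4). HSP101 then had -5.91 (SE 0.72), BAG6 -7.22 (SE 0.65) and HSFA7A -6.21 (SE 0.37), while ROF2 had -1.46 and HSP18.2, a small heat shock protein, 2.1 (SE 0.57, adjusted p = 0.0175). With TPM 859 genes were called and 84.7% rose, against 57.2% here, as the median of all genes moved by 0.22. The count was 734 and 1029 without WT heat replicates 1 and 2, 1070 without WT recovery replicate 3, and 1050 to 1104 without any 1 of siz1-2 room-temperature replicates 1, 2 and 3 and siz1-2 heat replicates 1 and 3. At most 1 heat stress factor, 1 reactive oxygen gene and 1 immunity gene fell without any 1 library other than the library labelled WT heat replicate 3.

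Recovery against room temperature in WT asked which transcripts had not returned. HSP18.2 had 3.68 scaled FPKM at room temperature and 1826 ± 677 after recovery (n = 1 and 3; log2 change 8.55, SE 1.87, adjusted p = 0.0395; joined). PAL2, which starts phenylpropanoid synthesis, rose from 11.96 to 77.1 ± 5.56 (log2 change 2.59, SE 0.22, adjusted p = 0.000392), and PCR1, a cadmium resistance protein, fell from 30.4 to 1.67 ± 1.21. AUR1, a mitotic kinase, fell from 7.99 to 3.60 ± 0.0343, and SNC1, an immune receptor, rose from 12.4 to 22.4 ± 2.01, against its list: of 18 immunity genes it alone passed, and 15 lay below 0 (median -0.42; camera adjusted p = 0.0299, downwards, and adjusted p = 0.557 with an estimated correlation). Photosynthesis genes split, and of 18 genes 1 rose, LHCB2.1 (log2 change 1.69), and 3 fell, LHCB3 (-1.31), LHCB1.3 (-1.50, joined) and LHCA4 (-1.35), or 2 and 8 adjusted over the list alone, while with FPKM as deposited 3 rose and 0 fell, and with TPM and with quantile normalization 1 rose and 0 fell. The library labelled WT heat replicate 3, which lacked the heat response, also differed from the room-temperature library in some of these genes. Its log2 differences were 2.12 for PAL2, -1.07 for LHCB3 and -0.84 for LHCA4. For such genes the single room-temperature library may stand apart, and the change need not be left over from heat. In all 292 genes passed, 197 higher and 95 lower, and in a limma fit of the WT room-temperature and recovery libraries alone 2 of 16011 did (1715 at an unadjusted p under 0.05). HSP18.2 lost its call without WT heat replicate 1, any 1 WT recovery library or any 1 siz1-2 library (adjusted p up to 0.0754), and SNC1 without WT recovery replicates 1 and 3 or any 1 siz1-2 library (up to 0.0824). Of the photosynthesis genes 2 rose and 5 fell without WT heat replicate 2, and 2 and 3 without WT recovery replicate 2.

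Without the library labelled WT heat replicate 3, 613 genes passed in this comparison. Of 10 small heat shock proteins 6 were above room temperature (7 adjusted over the list alone), with AT1G53540 at a log2 change of 9.79 (SE 0.47, adjusted p = 7.19e-06), HSP17.6II at 9.58 and AT2G29500 at 7.62. Of 18 larger chaperones 6 were above it (8 adjusted over the list alone), among them ROF2 at 7.21 and HSA32, which sustains thermotolerance, at 5.39, while HSP101 had 3.11 (adjusted p = 0.082). Set against the heat change, recovering seedlings held 94.9% of the log2 change of AT2G29500, 109.5% of AT1G53540 and 83.2% of ROF2, but 34.5% of HSP101, 15.6% of BAG6 and 9.1% of HSFA7A. The lists overlapped in this share, with HSA32 at 82% and HSP60 at 75.6% among larger chaperones and AT1G54050 at 48.1% and AT2G19310 at 36.7% among small heat shock proteins. AT1G53540, HSP101, HSA32 and AT1G54050 were joined in WT, while AT2G29500, ROF2, BAG6 and HSFA7A were not. Of 573 genes that rose at least 2-fold in heat, the median kept 34.2% (quartiles 9.2 and 60.9%), and of 434 that fell, 13.9% (quartiles -4.6 and 41.5%), while 442 and 402 of them did not pass against room temperature. Both changes share the room-temperature library. In 50 simulations with recovery at its level these medians were 5 to 8.5% and 8.7 to 12.7% from noise alone. The simulations selected a mean of 871 and 713 genes, against 573 and 434 here, so they differ from the data and give only a rough scale. On that scale, much of the share for genes that fell may need no kept change. With FPKM as deposited 4057 genes were called in this comparison and 99.4% rose, and with TPM 80 and 78.8%, against 67.5% here, as the median of all genes moved by 0.66 and 0.09. The count was 495 without WT heat replicate 2, 179 and 163 without siz1-2 room-temperature replicates 2 and 3, and 171 and 170 without siz1-2 heat replicates 1 and 3.

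Both WT comparisons share the single room-temperature library. Of the 100 genes called in heat, 59% were called in the same direction after recovery, 45 upwards and 14 downwards, where independent lists would share 1.3 and 0.2; the share was 12.5% without the library labelled WT heat replicate 3. Simulated groups without effects shared a mean of 2.56 and 2.48 genes (at most 10 and 9). Across genes the log2 changes had r = 0.569 and a covariance of 0.191, against 0.751 and 0.098 in the simulation. Part of the excess may come from the shared control.

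**Figure D3:**
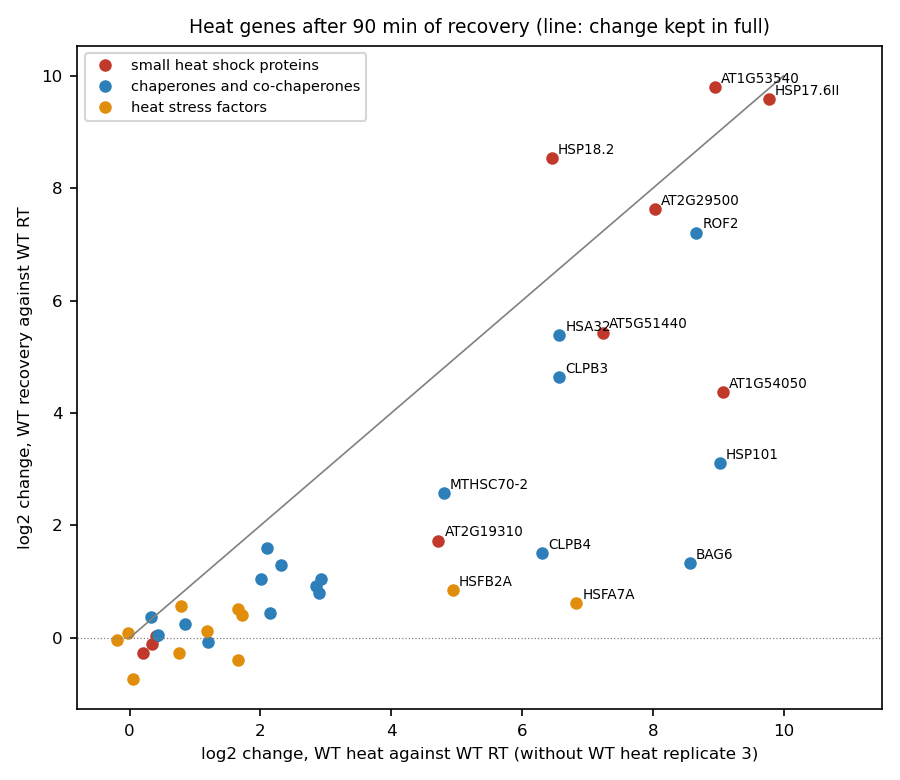
Log2 change in WT after recovery (vertical axis) against log2 change after heat without the library labelled WT heat replicate 3 (horizontal axis), both against the room-temperature library, for tested heat stress factors, small heat shock proteins and larger chaperones; points are genes and the line marks a change kept in full. AT2G29500 lies near the line (8.03 and 7.62), and HSP101 (9.02 and 3.11) and HSFA7A far under it.

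At room temperature, siz1-2 had lower mRNA of light-harvesting proteins than the WT library. LHCB3 was at 54.6 ± 4.02 scaled FPKM against 848 (n = 3 and 1; log2 difference -3.94, SE 0.19, adjusted p = 8.33e-07), LHCA4 (chromosome 3, 17493343 to 17495033) at 137 ± 14.8 against 1172 and LHCA3 at 91.0 ± 9.40 against 1052. Of 18 photosynthesis genes 13 were lower and 0 higher in the main scaling (15 adjusted over the list alone; camera adjusted p = 4.44e-15, and adjusted p = 0.504 with an estimated correlation), while with FPKM as deposited 9 were lower and 3 higher. The superoxide dismutases CSD1 and CSD2 were lower too, at 29.7 ± 2.92 against 222 and 30.0 ± 1.71 against 112. The single WT library was itself above the other WT libraries for some of these genes. Relative to it, heat replicates 1 and 2, the library labelled WT heat replicate 3 and the recovery mean had log2 differences of -1.16, -1.07 and -1.31 for LHCB3. These were -0.93, -0.84 and -1.35 for LHCA4 and -0.84, -1.19 and -0.66 for CSD2. Part of the differences from siz1-2 may belong to that library. SOC1 (chromosome 2, 18807505 to 18811125), which promotes flowering, was higher at 16.7 ± 2.47 against 3.20 (log2 difference 2.07, SE 0.26, adjusted p = 0.000807), as was PHR1, the main regulator of phosphate starvation genes, at 24.5 ± 0.738 against 6.09. COR15B, a cold-induced chloroplast protein, was lower at 1.53 ± 0.0125 against 14.1. Of 9 root markers 2 were higher and 0 lower, the same adjusted over the list alone (median 0.27; camera adjusted p = 0.319, and adjusted p = 0.914 with an estimated correlation). The count was 1 without siz1-2 room-temperature replicate 1 or siz1-2 heat replicate 2. Limma called 0 (2 at an unadjusted p under 0.05) without WT recovery replicate 1, siz1-2 room-temperature replicates 2 and 3 or siz1-2 heat replicates 1 and 3.

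In all 1042 genes differed, 574 higher and 468 lower in siz1-2. A fit of these libraries alone takes its whole spread from the 3 siz1-2 libraries, since WT had 1, so it holds no WT variation. Of 20 growth genes 4 were lower and 0 higher (8 adjusted over the list alone), with IAA19 at -1.38 and SAUR19 at -1.20, but with FPKM as deposited 9 were higher and 0 lower. Of 18 immunity genes 2 were higher and 0 lower (5 adjusted over the list alone; camera adjusted p = 0.0218, and adjusted p = 0.557 with an estimated correlation), NUDT6 at 0.95 and PAD3 at 0.93. PR1 (chromosome 2, 6241640 to 6242541), the marker of salicylic acid responses, had 10.09, 39.18 and 37.71 against 9.17 (log2 difference 1.35, SE 1.09, adjusted p = 0.537). HSP101 had 0.42 (adjusted p = 0.961), and limma called 0 of 17 larger chaperones (0 at an unadjusted p under 0.05) and 0 of 12 SUMO pathway genes (1 at that p). The test of the small heat shock proteins pointed up while their median was -0.22; 2 of 9 were higher. The steepest differences included joined genes, such as NRPA2 at -6.26, which overlaps LHCB1.3, and the unjoined AT4G20362 (chromosome 4, 10989908 to 10992242), at 2.69 ± 0.504 against 527. WT and siz1-2 files were made differently, as were the values of genes with several isoforms, and 302 of the 1042 genes were joined. With FPKM as deposited 8767 genes were called and 99.1% were higher, and with TPM 785 and 81.7%, against 55.1% here, as the median of all genes moved by 1.13 and 0.29. The count was 1725 without the library labelled WT heat replicate 3 and 661, 569 and 617 without siz1-2 room-temperature replicates 1, 2 and 3. Immunity genes that were higher numbered 6 without WT heat replicate 2 or 3, 1 without WT recovery replicate 2, siz1-2 room-temperature replicate 2 or any siz1-2 heat replicate, and 0 without siz1-2 room-temperature replicates 1 and 3 (limma; 7 and 6 at an unadjusted p under 0.05). Without the library labelled WT heat replicate 3, 7 growth genes and 2 of 18 larger chaperones were lower, and 1 of 12 SUMO pathway genes was higher. Small heat shock proteins that were higher numbered 1 without any 1 siz1-2 room-temperature library or siz1-2 heat replicates 1 and 3.

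After heat, siz1-2 had higher mRNA of salicylic acid and immunity genes than WT. Of 18 tested 10 were higher and 0 lower (13 adjusted over the list alone; camera adjusted p = 0.0057, and adjusted p = 0.504 with an estimated correlation), with 7 to 12 higher and 0 lower in the other scalings. PR1 was at 28.3 ± 22.6 scaled FPKM against 2.09 ± 0.926 (SD, n = 3 each; log2 difference 2.84, SE 0.77, adjusted p = 0.0214). AIG1, induced by avirulent bacteria, was at 8.17 ± 2.97 against 1.42 ± 1.13, and PBS3, an enzyme of salicylic acid synthesis, had a log2 difference of 1.48. PDF1.2, a defensin of the jasmonate pathway, was at 81.0 ± 25.8 against 5.64 ± 3.85, and BCB, a blue copper protein, at 433 ± 67.9 against 37.8 ± 39.2. Photosynthesis genes were lower in 11 of 18 and higher in 1, PSBO2, in the main scaling and adjusted over the list alone, with 9 to 11 lower and 1 higher in the others; LHCB3 was at 93.4 ± 14.2 against 388 ± 26.1. SOC1 was higher at 14.1 ± 1.36 against 3.12 ± 1.02. PR1 lost its call without WT heat replicates 1 and 3 and siz1-2 heat replicates 2 and 3 (adjusted p up to 0.0856), and 6 and 5 immunity genes were higher without WT heat replicate 1 and siz1-2 heat replicate 3.

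In all 2889 genes differed after heat, 1455 higher and 1434 lower in siz1-2, and 1913 of 12782 did in a fit of these libraries alone. Here too the WT and siz1-2 files were made differently, as were the values of genes with several isoforms. HSP101 was at 2341 ± 56.6 against 1490 ± 1628 (log2 difference 3.27, SE 1.94, adjusted p = 0.243). Of 17 larger chaperones 2 were higher (1 adjusted over the list alone; camera adjusted p = 0.0385, and adjusted p = 0.914 with an estimated correlation), HSP90.3 and HSP60. Without the library labelled WT heat replicate 3, 2 of 18 were higher and 1 lower, with a median of 0.07. Of 18 immunity genes 7 were higher without that library (10 adjusted over the list alone). SCE1, the SUMO conjugating enzyme, was the 1 of 12 SUMO pathway genes that passed, at 0.49 (0 adjusted over the list alone). Of 9 genes of abscisic acid, cold and drought 3 were lower, COR15B at -2.74, RD29A at -1.79 and RD22 at -0.99 (3 adjusted over the list alone). Genes called between genotypes overlapped across temperatures: 353 were higher and 340 lower in siz1-2 at both, where independent lists would share 72.0 and 57.8, and 11 went opposite ways. Part of this overlap may come from the differences in how files and gene values were made, which both comparisons share. The count was 1808, 1856 and 1872 without siz1-2 heat replicates 1, 2 and 3. Larger chaperones that were higher numbered 9 without WT heat replicate 2 and 1 without WT recovery replicate 1 or any 1 siz1-2 library, and SCE1 lost its call without WT heat replicate 1 or any 1 siz1-2 library.

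The response to heat was compared between genotypes directly. Across genes the log2 changes of WT and siz1-2 had r = 0.629 (Spearman's rho 0.482), and r was 0.743 (rho 0.604) without the library labelled WT heat replicate 3 and 0.42 without WT heat replicate 2. Without the first, 618 genes rose and 706 fell in both genotypes, where independent lists would share 166.9 and 170.2, and 40 went opposite ways; with it 6 and 8 did, against 6.7 and 2.6. The difference itself passed in 69 genes, 27 with a higher and 42 with a lower response in siz1-2, and in 208 of 12703 in a fit without the recovery libraries. In 64 of the 69 the library labelled WT heat replicate 3 had at least 50% of the WT change of the other heat libraries. The calls were made with that library in the WT heat group, which favours such genes, so this share was largely set by the call. As that library lacked the heat response, the WT change of these 64 need not be a response to heat. LHCA4 (1.96, SE 0.27, adjusted p = 0.0122), LHCB3 (1.88, SE 0.24, adjusted p = 0.00848) and PSBO2 (1.49, joined) had a higher response in siz1-2, and 3 of 18 photosynthesis genes passed (10 adjusted over the list alone), but with FPKM as deposited 1 was higher and 1 lower, and with TPM and quantile normalization 0 passed. For HSP101 the difference was 2.85 (SE 3.37, adjusted p = 0.789) and -0.18 without the library labelled WT heat replicate 3. For PR1 it was 1.50 (adjusted p = 0.713). For this difference limma called 0 of 17 larger chaperones (0 at an unadjusted p under 0.05), 0 of 9 small heat shock proteins (1 at that p, and 1 lower adjusted over the list alone) and 0 of 20 growth genes (5 at that p). With FPKM as deposited 6516 genes were called and 0.3% were higher, against 39.1% here, as the median of all genes moved by -0.998. TPM moved it by -0.28, with 16 genes called. The count was 295 and 151 without WT heat replicates 2 and 3 and 116 without WT recovery replicate 2. It was 26, 20 and 24 without siz1-2 room-temperature replicates 1, 2 and 3, and 23, 35 and 20 without siz1-2 heat replicates 1, 2 and 3. Without WT heat replicate 2, 6 photosynthesis genes passed, and PSBO2 was lost without WT heat replicate 1 or any 1 siz1-2 library (adjusted p up to 0.146).

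**Figure D4:**
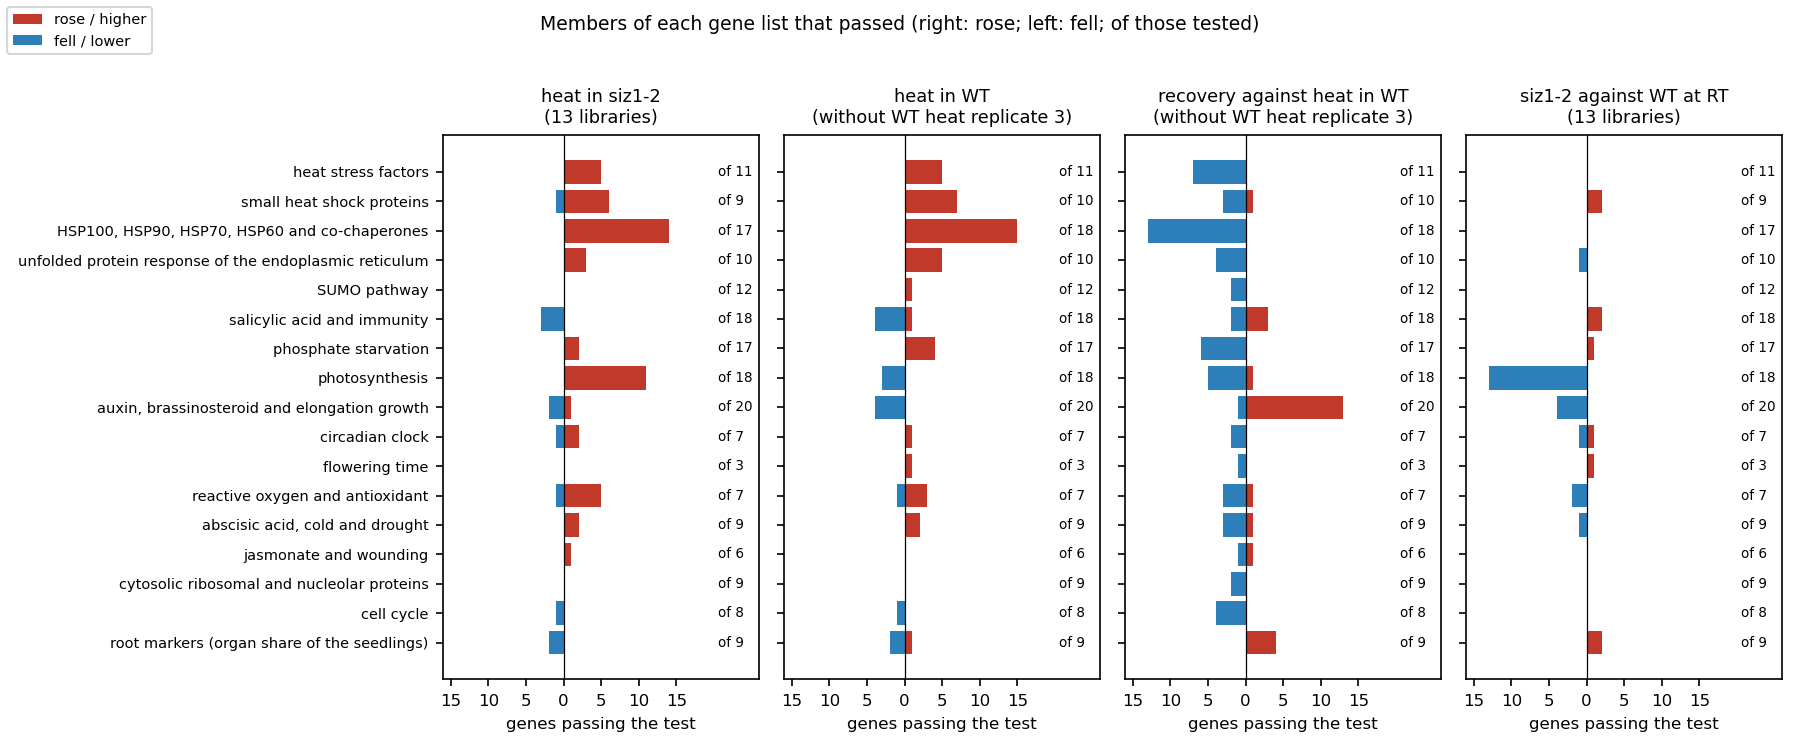
Members of each gene list that passed the test (right, higher; left, lower), with the number tested, for heat in siz1-2, heat in WT and recovery against heat in WT without the library labelled WT heat replicate 3, and siz1-2 against WT at room temperature. Larger chaperones rose in 14 of 17 in siz1-2 and 15 of 18 in WT after heat and fell in 13 of 18 in recovery.

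Of the 119 list tests over the 7 comparisons, 31 passed with camera's preset correlation and 0 with an estimated one (lowest adjusted p = 0.504, 8 at an unadjusted p under 0.05). In the fit of siz1-2 libraries alone, larger chaperones in heat held with an estimated correlation (adjusted p = 0.0251), with 21 of 22 genes higher. Median, mean and test did not all share a sign in 21 of the 119 tests, and 0 of these 21 passed with the preset correlation. A median or mean that rounded to 0 was counted as a different sign, so fewer of the 21 had opposite signs.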

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

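The tests of the library labelled WT heat replicate 3, of the differences between genotypes at room temperature and of the seed mRNAs were chosen after those results were seen, while the counts over other splits of the libraries were planned.

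The library labelled WT heat replicate 3 stood apart in its heat genes: the 194 genes that rose at least 4-fold in heated siz1-2 had a median log2 difference of -0.037 from the WT room-temperature library, against 2.14 and 3.41 in the other WT heat libraries. A weaker or shorter heat is argued against, because only 2.1% of these genes lay at least 1 above that library and 4.1% lay at least 1 below it. A swap with a library analysed here is argued against too, since the highest such median among the recovery libraries was 0.975; a swap with WT room-temperature replicate 1 or 3, not analysed here, stays open. An unheated sample, or one from outside these libraries, is a candidate explanation that needs a median near 0, as seen. Looking through all genes after the values were seen, AT5G60650 (56.75 scaled FPKM there, 58.03 and 59.66 in the other heat libraries, 2.1 to 2.9 in the rest of WT) and AT5G02950 (1.0, with 0.36 and 0.38 against 14.92 to 16.37) were at least 4-fold apart between heat and the other WT groups in all 3 heat libraries; no biological explanation was tested.

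The 1042 genes that differed between siz1-2 and WT at room temperature compare files that were made in different ways. For genes with several isoforms the gene values also had different divisors. A loss of reads shared between isoforms in siz1-2 cannot act directly on the 692 of them with 1 isoform, which have no such reads. It would move these only upwards through the scaling, which argues against it for the 43.4% (300) that were lower. For the 350 with 2 or more isoforms it cannot be told apart from other differences, because all siz1-2 files listed only 43.5% of such genes with a median WT FPKM of at least 10, and unlisted genes were not tested. Transcripts joined to a neighbour in WT, as flagged here, are argued against as the whole cause as well, since 29% of the genes (302) were joined, against 23.5% of all genes tested. Smaller sharing with a neighbour was not flagged and stays open. The siz1-2 genotype and the remaining differences in how the files and gene values were made cannot be told apart for these genes. All siz1-2 files were on cDNA sequences, where no transcript can span a pair of genes, while every WT file was on chromosomes and held such transcripts.

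SESA2, a seed storage albumin, had 25.52 scaled FPKM in siz1-2 heat replicate 2, outside the genes tested. It had 1.3 and 1.5 in siz1-2 heat replicates 1 and 3, 0.66 in room-temperature replicate 3 and was not listed elsewhere. Of the other seed maturation genes with a value, 5 of 5 were highest in that same library, among them SESA4 (16.63), SESA1 (9.03) and OLEO1 (6.47, against 3.76 in heat replicate 3). Some ungerminated seed or embryonic tissue in that sample may account for this, as it needs these genes to be highest together. No biological explanation was tested, since the design names no group to which that library alone belongs.

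The change from room temperature to heat differed between genotypes, by the test of the difference itself, in 16 named genes; values are log2 changes in siz1-2 minus those in WT. The change was higher in siz1-2 for EGY3, a chloroplast protein related to proteases (4.88), AT5G03285 (4.86), AT3G28220 (2.98), AT5G02950 (2.87), CCP2 (2.86), the profilin PRF3 (2.54), the superoxide dismutase CSD2 (2.12) and the photosynthesis genes LHCA4 (1.96), LHCB3 (1.88) and PSBO2 (1.49). It was lower for AT5G60650 (-4.27), the serine acetyltransferase SERAT3;2 (-3.89), AT5G16730 (-2.82), SIB2, which binds sigma factors (-2.75), AT2G21630 (-2.74) and PAL2 (-2.39). For 12 of the 16 the library labelled WT heat replicate 3 had at least 50% of the log2 change of the other heat libraries. The others were EGY3, AT5G03285, PRF3 and PSBO2. The calls were made with that library in the WT heat group, so this share was largely set by the call. As that library lacked the heat response, the WT change of these 12 need not be a response to heat. In 9 of these 12 the recovery mean also had at least 50% of that change, among them LHCB3 (-1.16 in heat replicates 1 and 2, -1.07 in the library labelled WT heat replicate 3 and -1.31 in recovery) and SERAT3;2 (4.08, 4.06 and 3.14). In siz1-2 AT5G02950 was already at 0.90 to 0.99 at room temperature, and AT5G60650 did not pass in heat (log2 change -0.045, adjusted p = 0.862). Of these 16 genes 8 were joined in WT and 16 passed without the library labelled WT heat replicate 3. In the 12 fits that each left out 1 library, 10 passed throughout. EGY3, CSD2, PSBO2 and CCP2 lost their calls without any 1 siz1-2 library, and AT5G16730 and SIB2 without any but siz1-2 heat replicate 2 (adjusted p up to 0.115, 0.11, 0.146, 0.0818, 0.0656 and 0.0915). EGY3, CSD2 and PSBO2 also lost theirs without WT heat replicate 1, and EGY3 without WT recovery replicate 3. When each transcript went to a single gene, 9 could be tested and 2 passed, AT3G28220 and AT5G02950. AT5G16730 and PAL2 then had smaller differences (-1.33 each, SE 0.31 and 0.37, against SE 0.43 and 0.27 before). EGY3 (4.87, SE 0.87, against SE 0.90 before) and CSD2 (1.96, SE 0.33, against SE 0.38) lost their calls at a similar size and SE, as their adjusted p rose to 0.0826 and 0.0711. LHCA4 (1.72, SE 0.33, against SE 0.27), LHCB3 (1.76, SE 0.62, against SE 0.24) and PSBO2 (1.69, SE 0.41, against SE 0.28) lost theirs with a larger SE.

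Other splits of the 6 libraries into 3 and 3 were counted for the comparisons with 3 libraries on each side; 10 splits are too few for a share under 0.05, and 1 of 10, the real one, reached the real count in each. For heat in siz1-2 the real count was 2232 and the highest other 0, and for siz1-2 against WT after heat 2889 and 0. For recovery against heat in WT the real count was 1718 and the highest other 293, from the split that set WT heat replicates 1 and 2 with recovery replicate 3.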

How the results depend on the processing

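Settings were planned except the single gene per transcript, leaving out joined genes, genes with 1 isoform, and leaving out WT heat replicate 3 with WT recovery replicate 1, which were added after seeing the data. Counts of genes are given in the order of the report where they moved by over 1.5 times, and the cause was not tested unless given. Of the values of named genes under other settings, 3359 kept their direction and side of the threshold, 464 lost the call, 6 gained one and 6 reversed.

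With FPKM as deposited the counts were 4288 (heat in siz1-2), 4147 (heat in WT), 694 (recovery against heat), 4057 (recovery against room temperature), 8767 (genotypes at room temperature) and 6516 (interaction), since this removes the scaling between libraries. TPM gave 22 for heat in WT, 859 and 80 for the recovery comparisons, 1590 for genotypes after heat and 16 for the interaction, and quantile normalization 159 for heat in WT. With unlisted genes kept as 0, heat in siz1-2 gave 1393, heat in WT 304, recovery against room temperature 504, genotypes 5711 and 7744, and the interaction 250; genes missing from siz1-2 files then count as lower. A change of at least 1 (log2) as a further threshold left 735, 446, 637 and 934 genes for heat in siz1-2, recovery against heat and genotypes at room temperature and after heat, as it only removes genes. In fits of only the groups compared, WT at room temperature adds no spread, as it had 1 library. Fits of only the groups compared gave 7978 for heat in siz1-2, 0 for heat in WT with limma (689 at an unadjusted p under 0.05), 15 and 2 for the recovery comparisons (2770 and 1715 at that p), 5590 and 1913 for genotypes and 208 for the interaction, with fewer libraries to estimate the spread and other genes tested.

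A single gene per transcript gave 31 for heat in WT, 918 and 114 for the recovery comparisons, 464 and 1598 for genotypes and 6 for the interaction, with fewer genes tested. Without joined genes the interaction had 39, and with genes of 1 isoform genotypes had 688 and 1876, again with fewer genes tested. Without WT heat replicate 3 and WT recovery replicate 1 together, counts were 4164, 2338, 4243, 865 and 2042 for heat in siz1-2, heat in WT, both recovery comparisons and genotypes at room temperature, and 239 for the interaction; the correlation of heat responses was 0.742, the share of heat-called genes still called after recovery 16%, and the HSP101 interaction -0.18. Of the gene list tests 30, 27, 28 and 30 passed with the preset correlation in these settings, against 31 in the report, where 0 passed with an estimated one.

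Leaving out 1 replicate at a time gave 245 to 3761 genes for heat in siz1-2, 55 to 2088 for heat in WT, 734 to 4249 for recovery against heat, 163 to 613 for recovery against room temperature, 569 to 1725 and 1808 to 4253 for genotypes at room temperature and after heat, and 20 to 295 for the interaction. The correlation of heat responses ranged from 0.42 to 0.743 and the share still called after recovery from 12.5 to 67.2%. PR1 in heated siz1-2 ranged from -0.89 to 0.59, above 0 without siz1-2 room-temperature replicate 2 or 3 or heat replicate 1. PR1 in recovery against heat ranged from -0.39 (without WT recovery replicate 2) to 0.68, and the HSP101 interaction from -0.18 (without WT heat replicate 3) to 4.72.

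With the replicate number as a block, heat in WT gave 51, recovery against room temperature 141 and the interaction 33 genes, and the other counts moved by less than 1.5 times. The numbers do not pair the samples: of 18 pairs of libraries with the same number 4 had deviations correlated above 0.1 (-0.18 to 0.18), and 4 of 12 libraries correlated best with their own number. Depth is known only as 6.62 to 11.4 Gb implied per library, so no counting interval could be given.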

Other observations

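The genes named here were chosen after their values were seen, and no explanation was tested for them. In heated siz1-2, FLS2, RLP23, NDR1 and NIMIN-2 were among the 15 largest falls when the spread was taken from siz1-2 libraries alone (limma, 14282 genes); they were picked by eye, with no test of enrichment. FLS2, the receptor for bacterial flagellin, had a log2 change of -2.01 (SE 0.12, adjusted p = 2.81e-06), RLP23, a receptor for a microbial peptide, -2.05 (SE 0.18), and NDR1, which acts downstream of resistance proteins, -1.96 (SE 0.14). NIMIN-2, a binding partner of NPR1, had -2.15 (SE 0.10), and outside these 15 the factors WRKY54 and WRKY60 had -1.53 (SE 0.15) and -1.51 (SE 0.11). Of 23 genes of the immunity list in that fit 10 fell and 2 rose, WRKY70 and SARD1, at 0.75 (SE 0.11) and 0.67 (SE 0.15); camera gave an adjusted p = 0.0417, and an adjusted p = 0.625 with an estimated correlation. Of 10 root markers, a list for the share of organs in a sample, 6 fell and 0 rose in that fit (median -0.46; camera adjusted p = 0.06, and adjusted p = 0.64 with an estimated correlation). IPT3, an enzyme of cytokinin synthesis, had -1.96 (SE 0.11). Of 18 phosphate genes 4 rose and 0 fell, with PAP17, an acid phosphatase, going from 38.0 ± 11.1 to 108 ± 10.5 as scaled in that fit (SD, n = 3 each). Clock genes went both ways, with 7 of 9 higher and 2 lower, GI at 1.25 (SE 0.13) and FKF1, which promotes flowering in long days, at -1.02 (SE 0.11).

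Some genes outside the tested set differed in which libraries listed them. FT, the mobile signal for flowering, had 1.54 to 3.92 scaled FPKM in all 6 siz1-2 libraries and was listed in WT only in heat replicate 2 (0.71) and recovery replicate 3 (0.60). PCC1, a gene induced by pathogens, had 86.07, 126.92 and 154.04 in siz1-2 at room temperature against 11.21 in the WT library, and 31.13 in the library labelled WT heat replicate 3 with 1.85 in heat replicate 1. These were not tested in the fit of all 13 libraries, and the files of the genotypes were made in different ways, as were values of genes with several isoforms. BIP3 had 44.92 in WT recovery replicate 3 and 1.05 and 1.69 in recovery replicates 1 and 2.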
